A study of Mus musculus with 16 samples.

How the data were processed

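RNA was measured by sequencing in 16 whole fetal brains of CD1 outbred mice at gestation day 18. Per the labels' protocols, the dams arrived on gestation day 4, were assigned at random on day 5 to a protein-sufficient or a protein-deficient diet, and were given a sham or an infection on days 5, 10 and 15. The series title names the infection as a nematode infection. Each of the 4 combinations of diet and infection has 4 libraries, numbered 1 to 4. Nothing in the labels says whether the 4 fetuses of a group came from separate litters, so every p-value measures the spread between these samples, which may be litter mates, and not the spread between dams.

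The deposited files hold whole-number read counts per Ensembl gene ID, which the authors made with HTSeq, per the submitters' processing notes. The same notes give the genome build as mm9. The aligner, the annotation release, the strand setting and the library kit are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and counts of near-identical pseudogenes and paralogs are uncertain. Each file lists 46603 gene IDs, of which 46005 were paired with a symbol from a reference gene table. The IDs run up to number 108299, and no coordinates are given. Library totals lay between 24393850 and 29945315 counts. Intervals and limits from single libraries cover counting error only.

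Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr over the 4 groups, which left 17688, and libraries were scaled with trimmed-mean (TMM) factors. One quasi-likelihood fit with robust dispersion gave each of the 4 groups its own mean and shared 1 estimate of the spread. From it came the infection effect over both diets, the diet effect over both infection levels, their interaction, and the 4 effects of 1 factor within a level of the other. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Log2 changes carry the standard error (SE) of that fit. CPM values are edgeR counts scaled by the TMM-adjusted library total.

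Of 40 gene lists written from textbook knowledge, 38 were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists within each of the 3 factorial comparisons. The replication-dependent histones had fewer than 5 tested members and were not tested, and the sex-linked genes are given as values. Of the 955 listed symbols, 4 matched no ID. Camera with an estimated correlation and fry, a rotation test of a list's own genes, stand beside it. The comparisons, tests, lists, other settings and the rule for naming genes were fixed before the data were examined. The rule names, per factorial comparison, up to 12 called genes in each direction. With fewer than 10 calls it names the 5 genes with the smallest p in each direction. It also names the 4 members with the smallest p of each called list, 2 members of any other list described, and 5 sex-linked genes.

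The other settings fixed beforehand were relative log expression scaling, the Wald test of DESeq2 1.42.0, no filter beyond 1 count, a mean CPM of at least 1, non-robust dispersion, limma voom with sample quality weights, and the replicate number as a block. Fetal sex as a covariate, svaseq surrogate variables (sva 3.50.0, at most 3), fits of only the groups compared, camera on ranks, and leaving out each library in turn completed them. The following were added after the data had been seen. The 4 libraries with a transcript length slope under -0.2 were left out. A lowess trend of each library on transcript length and GC content served as an offset, alone and with those 4 left out. Lengths came from a later annotation, for 17607 of the 17688 genes. The longest annotated transcript was tried first, and the principal transcript replaced it once results had been seen, so both are reported. DESeq2 was run with its independent filtering off and on, and taking the version without it as the planned one was decided after both counts had been seen.

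The steps were tested on simulated counts drawn from the real means and library sizes. Each gene was drawn independently, without the length trend or the correlation between genes of the real data. The numbers that follow test the steps and do not give power or error rates for these data. Of 100 genes changed by 1 on the log2 scale, 47 were recovered in the infection comparison (17667 genes in that step), 40 in the diet comparison (17663 genes) and 3 in the interaction (17664 genes). Of 100 genes changed by 2, the numbers were 91, 96 and 47. In the infection effect on the sufficient diet (17659 genes) they were 17 and 72. Unchanged genes called numbered 6, 6, 1 and 4. Among 24 pairs of replicates, the chi-square per gene ran from 8.5 to 526, so no pair was a repeat of the same library. Figures were drawn with matplotlib 3.10.9. No library was left out of the fit reported first. Results for 2 single genes that the naming rule would include are not reported here, and both stay in all fits and list tests.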

Results

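Gene expression was counted in 16 libraries of total RNA from whole fetal mouse brain at gestation day 18. The 4 groups, of 4 libraries each, are named by maternal diet and infection: sufficient-uninfected, sufficient-infected, deficient-uninfected and deficient-infected. Totals ran from 24393850 counts in deficient-uninfected replicate 2 to 29945315 in deficient-infected replicate 4, and each library had counts for 23331 to 24143 genes. Totals averaged 27.4 ± 1.16 M counts in infected-dam and 27.1 ± 2.12 M counts in uninfected-dam libraries (SD, n = 8 each; exact two-sided permutation p = 0.732, adjusted p = 0.878 over 12 such comparisons of library measures).

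Sex-linked transcripts split the libraries into 7 female and 9 male brains. Xist, the RNA that silences an X chromosome, had 341 to 744 CPM in the female libraries and 0.0484 to 0.443 CPM in the male ones. The Y-linked genes ran the other way. In males Ddx3y had 52.6 to 102 CPM, Eif2s3y 37 to 220 CPM, Kdm5d 28.5 to 36.2 CPM and Uty 20.5 to 56.7 CPM. In females none of the 4 exceeded 0.0742 CPM, which lies under the 0.095 to 0.145 CPM that a count of 0 allows in these libraries. Females numbered 1 of 4 sufficient-uninfected, 2 of 4 sufficient-infected, 1 of 4 deficient-uninfected and 3 of 4 deficient-infected libraries. Uninfected dams gave 2 and infected dams 5 females (Fisher's exact two-sided p = 0.315).

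By transcript length, 4 libraries stood apart from the rest, all of uninfected dams: sufficient-uninfected replicates 1 and 3 and deficient-uninfected replicates 1 and 2. Genes with transcripts under 1000 bases stood 0.62 to 1.06 above their mean (median log2 CPM) in these libraries, and genes over 8000 bases stood at -1.6 to -0.7. Short abundant transcripts were prominent among them. Tuba1a, an alpha-tubulin of growing neurons, took 3.34% of all counts in sufficient-uninfected replicate 1 (95% Wilson interval 3.33 to 3.34), 2.73% in its replicate 3 (2.72 to 2.73), 2.4% in deficient-uninfected replicate 1 (2.4 to 2.41) and 2.19% in its replicate 2 (2.18 to 2.2). In the other 12 libraries it took 0.698% (0.695 to 0.701) to 1.45% (1.44 to 1.45). The slope of log2 CPM on log2 transcript length was -0.61, -0.44, -0.3 and -0.43 in the 4 libraries and -0.02 to 0.3 in the others. The first principal component held 68.6% of the variance and separated the same 4.

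**Figure D1:**
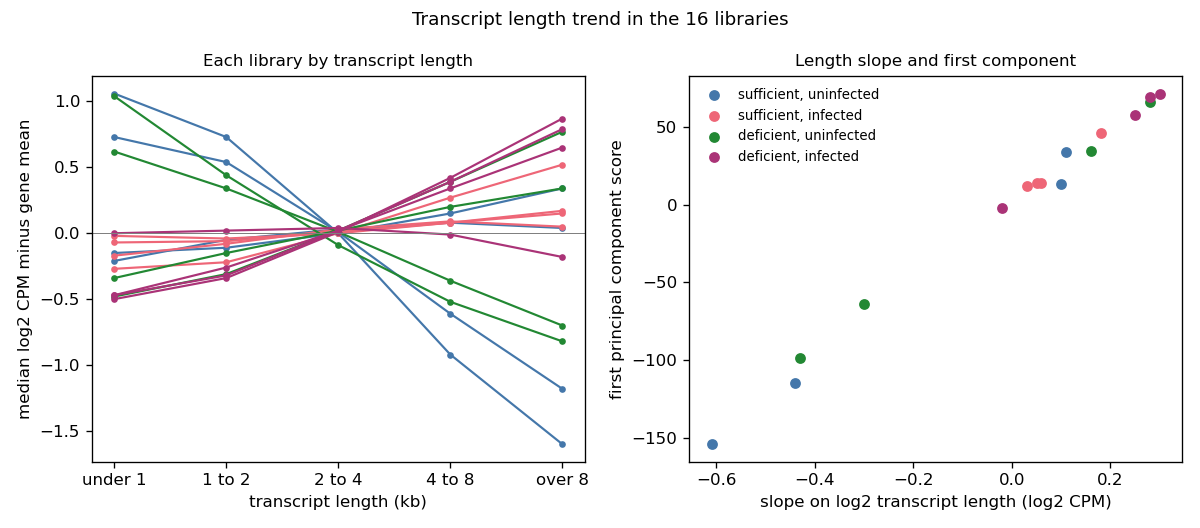
Left, median log2 CPM of genes in 5 transcript length classes (kb), relative to each gene's mean, with 1 line per library coloured by group; right, each library's slope on log2 transcript length (log2 CPM) against its score on the first principal component. The 4 libraries with slopes of -0.61 to -0.3 have the lowest scores, and all 4 come from uninfected dams.

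By infection, the length slope averaged 0.141 ± 0.124 in infected-dam and -0.141 ± 0.338 in uninfected-dam libraries (SD, n = 8 each; exact permutation p = 0.0494, adjusted p = 0.214). The share of Tuba1a averaged 1.08% ± 0.254 and 1.84% ± 0.95 (exact permutation p = 0.0535, adjusted p = 0.214). By diet the slopes averaged 0.0649 ± 0.285 (deficient) and -0.0649 ± 0.291 (sufficient; exact permutation p = 0.394, adjusted p = 0.604). The labels give no library or sequencing batch. Across genes, which are not independent replicates, transcript length had a Spearman correlation of 0.62 with the log2 change by infection and 0.55 with that by diet.

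The first question is what maternal nematode infection changed in the fetal brain, taken over both diets. Genes of protein synthesis and respiration were lower in infected-dam brains as groups, and genes of neuronal signalling were higher. The cytosolic ribosomal proteins were lower by a mean log2 change of -0.77, with 0 of 76 members higher (camera adjusted p = 3.39e-16). Nuclear genes of oxidative phosphorylation were at -0.64, with 58 of 59 members lower (adjusted p = 9.5e-13). Synapse and long-term potentiation genes were at 0.47, 42 of 51 members higher (adjusted p = 0.00101). Markers of glutamatergic neurons were at 0.53 with 18 of 20 higher (adjusted p = 0.00421), and markers of cerebellum and hindbrain at 0.77 with 19 of 22 higher (adjusted p = 0.0232). For each of these 5 lists the adjusted p was 0.865 with an estimated correlation between genes, and none passed with fry, whose smallest adjusted p was 0.229. With each library left out in turn, the means ran from -0.93 to -0.59, -0.76 to -0.49, 0.33 to 0.6, 0.38 to 0.67 and 0.34 to 1.06.

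These 5 differences rest on the 4 libraries that stood apart by transcript length. The ribosomal list stood at 0.79 to 1.35 above its mean in those 4 and at -0.75 to -0.13 in the other 4 uninfected-dam libraries, against -0.79 to -0.01 in the 8 infected-dam libraries. In a fit without the 4 (chosen after the data were seen) the ribosomal mean was 0.00 (adjusted p = 0.539), oxidative phosphorylation -0.01 (adjusted p = 0.539), synapse -0.02 (adjusted p = 0.44), glutamatergic neurons 0.06 (adjusted p = 0.275) and cerebellum and hindbrain 0.05 (adjusted p = 0.985). With a length and GC offset on all 16 libraries, also chosen after the data were seen, the ribosomal mean was -0.41 (adjusted p = 8.98e-14) and oxidative phosphorylation -0.3 (adjusted p = 7.53e-11), both still called. The calls of synapse (0.16, adjusted p = 0.0582), glutamatergic neurons (0.27, adjusted p = 0.0582) and cerebellum and hindbrain (0.65, adjusted p = 0.0593) ended. Dropping only deficient-uninfected replicate 1 took the cerebellum and hindbrain list to 0.34 (adjusted p = 0.172). That list also lost its call without sufficient-uninfected replicate 2 (adjusted p = 0.0623) or 4 (adjusted p = 0.117), or sufficient-infected replicate 1 (adjusted p = 0.0577), and with camera on ranks (adjusted p = 0.0824).

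**Figure D2:**
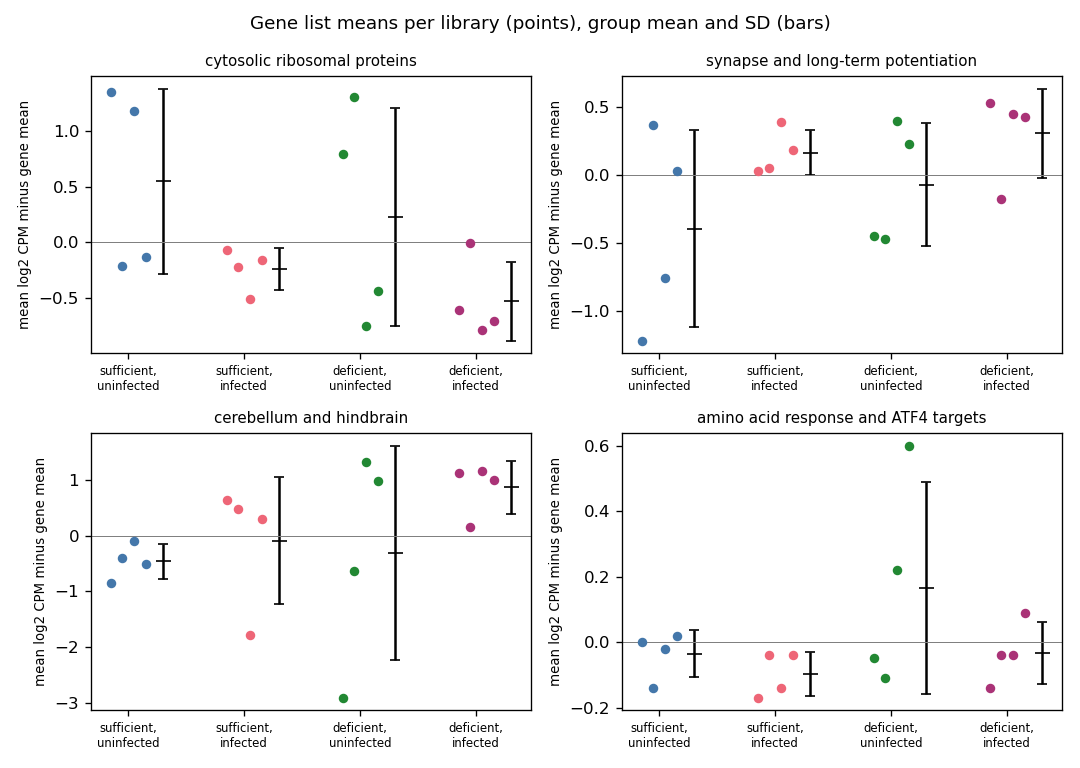
Mean log2 CPM of 4 gene lists, relative to each gene's mean over the 16 libraries, for each library (points) by group, with the group mean and SD (bars, n = 4). In the ribosomal panel, 4 uninfected-dam libraries lie at 0.79 to 1.35 and the other 12 at or below -0.01.

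Among members, the ribosomal protein genes Rps2 (log2 change -0.81, SE 0.21), Rpl13a (-1.44, SE 0.41), Rps24 (-1.32, SE 0.38) and Rps12 (-1.37, SE 0.41) each had an edgeR adjusted p of 0.131. Adjusted over the list alone, 74 of the 76 ribosomal members passed, all lower, against 0 when adjusted over all genes tested. For oxidative phosphorylation these numbers were 53 and 0. The estimated correlation between members was 0.95 in the ribosomal and 0.88 in the oxidative phosphorylation list. Both lists had already been called in these data, so the counts of members add no separate evidence. The respiratory chain subunits Cox6c (-0.98, SE 0.3), Cox7c (-1.14, SE 0.35), Uqcrq (-1.13, SE 0.35) and Ndufb7 (-0.94, SE 0.29) led the oxidative phosphorylation list. In the synapse list, members with small p were lower although the list mean was higher. Among them were the calmodulin gene Calm2 (-0.7, SE 0.24), the membrane fusion gene Snap25 (-0.46, SE 0.18) and the small GTPase gene Rap1a (-0.5, SE 0.2). With a length and GC offset Calm2 was at 0.02, and Rap1a turned to 0.02 with the longest-transcript version of it. Foxp2 (0.47, SE 0.24), Nhlh1 (0.88, SE 0.45), Neurod1 (0.42, SE 0.21) and Tle4 (0.34, SE 0.18), all transcription regulators, led the glutamatergic list. Barhl1 (0.67, SE 0.43), Reln (0.62, SE 0.4), Lhx5 (0.53, SE 0.35) and En1 (0.54, SE 0.38) led the cerebellum and hindbrain list. In the fit without the 4 libraries, Reln was at 0.00, Lhx5 at -0.03 and En1 at -0.07. In these last 3 lists 0 members passed over the list alone or over all genes.

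No single gene passed for infection: edgeR called 0 of 17688 genes, with a smallest adjusted p of 0.131. At an unadjusted p under 0.05 there were 4891 genes, 788 higher and 4103 lower, where 884 would be expected by chance. DESeq2 called 7 genes without independent filtering and 736 with it, and limma voom with sample quality weights called 0. Unadjusted, there were 2598 genes with fetal sex as a covariate (346 higher), 1881 with voom weights (988 higher) and 428 with svaseq (255 higher). The 7 DESeq2 genes, named after their values were seen, were Tnnt1, Rps3a2, Gm8399, Atf4, 2610042L04Rik and Xlr3b (lower) and Glns-ps1 (higher). With the 4 libraries left out, the edgeR counts were 0 adjusted and 454 unadjusted. The unadjusted count moved to 8850 without sufficient-uninfected replicate 2 and to 7952 without deficient-uninfected replicate 3. It moved to 2941 without sufficient-uninfected replicate 1 and to 3119 without deficient-uninfected replicate 2. Without sufficient-uninfected replicate 2, the pseudogene Gm8399 alone was called (adjusted p = 8.45e-05, log2 change -2.13).

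The genes with the smallest p, none of which passed, included Atf4, a transcription factor of the response to amino acid shortage. Atf4 stood at 284 ± 131 CPM in sufficient-uninfected, 153 ± 11.5 in sufficient-infected, 253 ± 44.1 in deficient-uninfected and 140 ± 21.8 in deficient-infected brains (SD, n = 4 each; log2 change -0.88, SE 0.19, edgeR adjusted p = 0.131). The 4 libraries of steep length slope had 268 to 415 CPM of Atf4, and the other 12 had 119 to 255 CPM. The other 4 on the lower side were Tnnt1, a troponin of slow muscle (-1.45, SE 0.28), the ribosomal pseudogene Rpl31-ps15 (-1.03, SE 0.22), the meiotic recombinase gene Dmc1 (-1.36, SE 0.3) and Gm8399 (-1.94, SE 0.43). Gm8399 had 62.6, 86.1 and 77.2 CPM in 3 sufficient-uninfected libraries and 2 to 4.34 CPM in the other 13. On the higher side were the pseudogenes Gm5388 (1.13, SE 0.22), Glns-ps1 (2.38, SE 0.53) and Gm11407 (0.98, SE 0.24), the locus Gm10676 (1.75, SE 0.35) and Myh3, a fetal muscle myosin (1.05, SE 0.23). The pseudogene counts depend on how reads shared with other loci were assigned.

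The remaining 33 lists were not called for infection in the fit of all 16 libraries. Among neuron and glia lists, the means were -0.29 for hypothalamic neurons (adjusted p = 0.0913), 0.01 for GABAergic neurons (0.952), 0.41 for monoaminergic neurons and receptors (0.221), 0.33 for neural progenitors and radial glia (0.178), 0.31 for the oligodendrocyte lineage and myelin (0.195), 0.2 for astrocytes (0.546) and 0.07 for choroid plexus and ependyma (0.952). Within the hypothalamic list, the hormone precursors Pomc (-3.04, SE 0.89) and Trh (-0.89, SE 0.25) were lowest in p. Among immune and vascular lists, microglia and macrophages were at -0.17 (0.432), neutrophil granule and alarmin genes at -0.62 (0.071), type 2 immunity at -0.23 (0.382), interferon-stimulated genes at 0.01 (0.995), NF-kB and inflammatory cytokine genes at 0.09 (0.952), endothelium and pericytes at 0.37 (0.29) and erythroid cells at 0.05 (0.952). Among tissues that a dissection can carry along, skin and oral or nasal epithelium were at -0.23 (0.221), skeletal muscle at -0.12 (0.813), eye at -0.13 (0.551), pituitary at -0.08 (0.892) and meninges, bone and cartilage at 0.1 (0.952).

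Response and metabolic lists were not called for infection in that fit either. The amino acid response and ATF4 targets were at -0.13 (adjusted p = 0.0767; called with the length and GC offset at -0.21, adjusted p = 0.00127), the unfolded protein response at -0.1 (0.382), p53 targets at -0.1 (0.382), the heat shock response at 0.01 (0.952), hypoxia and glycolysis at -0.01 (0.952), the glucocorticoid response at 0.05 (0.952) and immediate early genes at 0.17 (0.604). Calls with the offset in this paragraph used the preset correlation alone. Without the offset, the amino acid list had an adjusted p of 0.865 with an estimated correlation and 0.265 with fry. For the mitochondrially encoded list these were 0.986 and 0.742. The insulin and IGF axis stood at 0.39 (0.0601), imprinted growth genes at 0.24 (0.498), cholesterol synthesis at 0.06 (0.72), one-carbon metabolism and DNA methylation at 0.16 (0.813), the cell cycle at 0.06 (0.952), mitochondrially encoded genes at 0.15 (0.534; called with the offset at 0.96, adjusted p = 5.9e-05) and nuclear-retained and small structural RNAs at -0.22 (0.859). In the 4 libraries of steep length slope, the mitochondrially encoded list stood at -0.64 to 0.69 without the offset and at -2.2 to -0.28 with it. That call therefore came from the shift that the offset itself made. The mean was higher but the median lower for cholesterol synthesis (-0.04), choroid plexus and ependyma (-0.03), erythroid cells (-0.11), the glucocorticoid response (-0.07), the heat shock response (-0.07) and interferon-stimulated genes (-0.06). For pituitary (median 0.24) and hypoxia and glycolysis (median 0.01) the median was higher and the mean lower. The test pointed up for cholesterol synthesis, choroid plexus, interferon-stimulated genes, pituitary and hypoxia, and down for erythroid cells, glucocorticoid and heat shock genes. It also pointed down for GABAergic neurons, whose mean and median (0.04) were higher.

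Without the 4 libraries, genes that answer amino acid shortage had the smallest adjusted p by infection. The amino acid response and ATF4 targets were lower in infected-dam brains by a mean of -0.24, and they passed with the preset correlation (adjusted p = 6.85e-29) and with an estimated one (adjusted p = 0.0473), but not with fry (adjusted p = 0.051). Over the list alone 15 members passed, all lower, and 0 passed over all genes tested. This fit was chosen after the data were seen. Its interaction for the list was -0.41 (adjusted p = 1.95e-13, 0.208 with an estimated correlation and 0.26 with fry). On the sufficient diet the list stood at -0.14 and 0.02 in the 2 uninfected libraries kept and at -0.17 to -0.04 in the infected ones. The difference came with high values in 2 deficient-uninfected libraries, replicates 3 and 4, where the list stood at 0.22 and 0.6, against -0.17 to 0.09 in the 8 infected-dam libraries. Chac1, a glutathione-degrading enzyme induced by ATF4, had 19.7 and 31.5 CPM in these 2 and 5.14 to 10.3 CPM in the other 14. Mthfd2 of mitochondrial folate metabolism had 46.7 and 58.8 CPM in them and 15.5 to 30.2 CPM elsewhere, and the stress gene Sesn2 had 29 and 34.4 CPM against 2.86 to 19.4 CPM. Chac1 and the other 2 genes were named after their values were seen. Cholesterol synthesis genes were higher by 0.16 in this fit (adjusted p = 1.25e-10, and 0.179 with an estimated correlation). Another 7 lists were called in it with the preset correlation only: hypothalamic neurons (-0.34, adjusted p = 5.73e-08), erythroid cells (-0.38, 0.00339), neutrophil granule and alarmin genes (-0.34, 0.00339), the unfolded protein response (-0.06, 0.0198), and astrocytes (-0.08), meninges, bone and cartilage (-0.18) and mitochondrially encoded genes (0.23), each with an adjusted p of 0.0418. Of these, erythroid cells, astrocytes and meninges had means of the opposite sign with all 16 libraries.

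**Figure D3:**
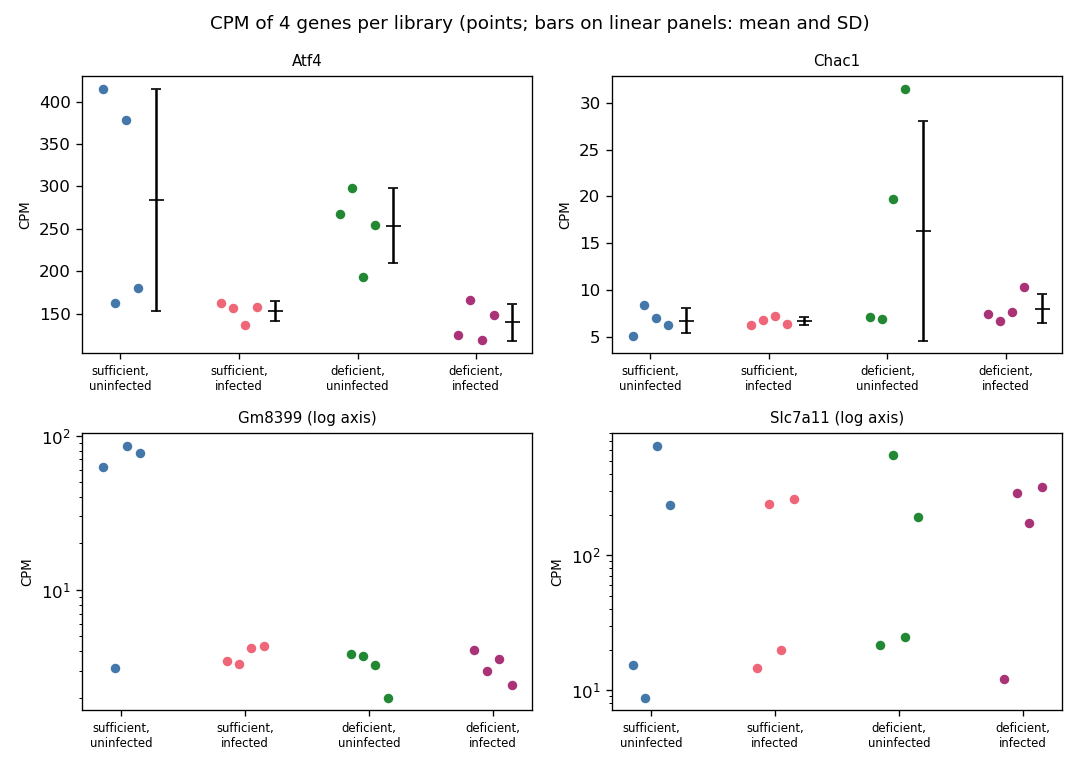
CPM of Atf4, Chac1, Gm8399 and Slc7a11 in each library (points) by group; the lower panels have log axes and the upper ones show the group mean and SD (bars, n = 4). Chac1 reaches 19.7 and 31.5 CPM in 2 deficient-uninfected libraries and at most 10.3 CPM elsewhere.

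The second question is what a low-protein maternal diet changed, taken over both infection levels. By camera with the preset correlation, ribosomal, respiratory, neutrophil, interferon and epithelial genes were lower as groups in brains of the deficient diet. Hindbrain, synapse and mitochondrially encoded genes were higher. With an estimated correlation 0 lists passed for diet (smallest adjusted p = 0.664), and with fry also 0 (smallest adjusted p = 0.651). By group means alone, the interferon difference lay in infected dams and the mitochondrial one in uninfected dams, though neither level was tested alone. The interaction of these lists, given below, was called with the preset correlation only. Its adjusted p was 0.204 and 0.353 with an estimated correlation, and 0.92 and 0.974 with fry. The largest list mean among the 8 called was that of neutrophil granule and alarmin genes at -0.66, with 10 of 11 members lower (camera adjusted p = 4.95e-06, and 0.664 with an estimated correlation; -0.85 to -0.55 over single libraries left out). The list stood at 0.74 to 1.31 in sufficient-uninfected replicates 3 and 4, sufficient-infected replicate 2 and deficient-uninfected replicate 2, and at most at 0.19 in the other 12. The same 4 had 1.89 to 5.21 CPM of Hp, a liver product, against at most 0.408 CPM elsewhere, and were among 6 libraries with 39 to 166 CPM of albumin (Alb). Hp and Alb were named after their values were seen. Over the list alone 2 members passed, against 0 over all genes tested. They were the granule protein gene Ngp (-1.33, SE 0.35), at 1.41 ± 0.782 CPM in sufficient-uninfected and 0.475 ± 0.0872 CPM in deficient-uninfected brains (SD, n = 4 each), and the iron-binding Lcn2 (-1.12, SE 0.32). Prtn3 (-0.36, SE 0.19) and Stfa2l1 (-0.99, SE 0.57) followed. Interferon-stimulated genes were at -0.24 with 16 of 20 lower (adjusted p = 0.00155, and 0.803 estimated; -0.3 to -0.18 over single libraries left out), led by Gbp3 (-0.53, SE 0.17), Bst2 (-0.58, SE 0.24), Xaf1 (-0.64, SE 0.32) and Isg15 (-0.61, SE 0.33). The list mean was -0.04 (sufficient) and 0.02 (deficient) in uninfected dams, and 0.27 and -0.26 in infected dams. A stricter filter on mean CPM ended that call (-0.15, adjusted p = 0.0809).

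Hindbrain markers were higher on the deficient diet by a mean of 0.55, in 21 of 22 members (adjusted p = 0.00182, and 0.803 estimated; 0.27 to 0.98 over single libraries left out). The developmental regulators Pax2 (1.63, SE 0.76), Egr2 (0.35, SE 0.17), Zic1 (0.39, SE 0.2) and Hoxb3 (1.23, SE 0.64) led that list. The list mean was -0.46 (sufficient) and -0.31 (deficient) in uninfected dams, and -0.09 and 0.86 in infected dams. Its call was lost without sufficient-infected replicate 3 (0.27, adjusted p = 0.109), where the list stood at -1.78, and without deficient-uninfected replicate 3 (0.28, adjusted p = 0.0542). Without the 4 libraries of steep length slope it was at 1.27 (adjusted p = 3.21e-10, and 0.662 estimated), and 13 members passed over the list alone. That fit leaves out deficient-uninfected replicate 1, where the list stood at -2.9, the lowest value of any library. In the others left out it stood at -0.84 to -0.09. The larger mean may therefore reflect the loss of that library and need not mean a stronger diet effect. Hoxb3 had 0 CPM in deficient-uninfected replicate 1 and 0.292 CPM in sufficient-infected replicate 3, against 0.635 to 6.33 CPM in the others. Whether the brains held like shares of hindbrain tissue was not tested for any comparison of this list. Synapse genes were at 0.23 (adjusted p = 0.0169, and 0.834 estimated), with Grin2c (0.33, SE 0.21), Grin1 (0.38, SE 0.26) and Adcy8 (0.5, SE 0.35) higher and Syp (-0.15, SE 0.1; 0.00 with voom weights) lower. They lost their call with the length and GC offset (0.06, adjusted p = 0.45; longest transcript 0.05, adjusted p = 0.573), without the 4 libraries (0.12, adjusted p = 0.242), and without any one of sufficient-uninfected replicate 1 (0.09, adjusted p = 0.471) or 3 (0.17, adjusted p = 0.0697), sufficient-infected replicate 1 (0.21, adjusted p = 0.0566), deficient-uninfected replicate 3 (0.15, adjusted p = 0.0647) or 4 (0.18, adjusted p = 0.0678), or deficient-infected replicate 1 (0.2, adjusted p = 0.0522).

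Ribosomal proteins were at -0.31 on the deficient diet, with 75 of 76 lower (adjusted p = 2.66e-09, and 0.803 estimated), and without the 4 libraries they were at -0.36 (adjusted p = 4.21e-18, and 0.662 estimated). Over single libraries left out the mean ran from -0.48 to -0.14, and that of oxidative phosphorylation from -0.41 to -0.13. Rps2 (-0.35, SE 0.21), Rps26 (-0.3, SE 0.19), Rpl11 (-0.4, SE 0.3) and Rpsa (-0.35, SE 0.3) led the list. Oxidative phosphorylation was at -0.26, with 58 of 59 lower (adjusted p = 2.52e-08, and 0.803 estimated), led by Cox8a (-0.33, SE 0.2), Ndufv1 (-0.27, SE 0.17), Ndufa13 (-0.23, SE 0.17) and Sdhc (-0.34, SE 0.25). A length and GC offset took the ribosomal mean to -0.17 and the respiratory mean to -0.14. The libraries kept in the fit without the 4 still differed in length slope by diet, so that fit does not separate diet from length. Their slopes were 0.03 to 0.18 on the sufficient diet. On the deficient diet they were 0.16 to 0.3, apart from deficient-infected replicate 2 at -0.02. Mitochondrially encoded genes were at 0.32, all 13 higher (adjusted p = 0.000326, and 0.803 estimated), led by mt-Nd4l (0.8, SE 0.4), mt-Atp8 (0.52, SE 0.26), mt-Nd6 (0.33, SE 0.17) and mt-Nd5 (0.38, SE 0.2). Over the libraries mt-Nd4l had only 0.244 to 2.83 CPM and mt-Atp8 1.05 to 5.8 CPM, against 89.4 to 260 CPM for mt-Nd6 and 319 to 1220 CPM for mt-Nd5. The list mean was -0.43 (sufficient) and 0.28 (deficient) in uninfected dams, and 0.11 and 0.04 in infected dams. That call was lost without the 4 libraries (0.12, adjusted p = 0.433), without sufficient-uninfected replicate 4 (0.23, adjusted p = 0.0602) and without deficient-uninfected replicate 2 (0.26, adjusted p = 0.0501). Skin and oral or nasal epithelium genes were at -0.24 (adjusted p = 0.0118, and 0.664 estimated), with Omp (-1.09, SE 0.52), Krt19 (-0.34, SE 0.16) and Krt18 (-0.37, SE 0.2) lower and Dsp (0.68, SE 0.39) higher. They lost it without the 4 libraries (-0.2, adjusted p = 0.247), with the mean CPM filter (-0.14, adjusted p = 0.14), without deficient-uninfected replicate 2 (adjusted p = 0.0539) and without deficient-infected replicate 2 (adjusted p = 0.0775). In the lists of this comparison other than the neutrophil one, 0 members passed over the list alone in the fit of all 16 libraries, and with fry 0 of the 38 lists passed (smallest adjusted p = 0.651).

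For diet edgeR called 0 of 17688 genes (smallest adjusted p = 0.784), with 324 genes at an unadjusted p under 0.05 against 884 expected by chance. DESeq2 called 2 with or without independent filtering, Gm8399 and the pseudogene Rps2-ps10, both lower. Voom with sample quality weights called 2563, 1272 higher and 1291 lower. In that fit deficient-uninfected replicate 4 had a weight of 10.8, and the others of its group 0.109 to 1.05. The mean of that group therefore rested mostly on that library. The unadjusted count was 7634 with voom weights, 688 with svaseq and 285 with fetal sex as a covariate. Leaving out the 4 libraries gave edgeR counts of 0 adjusted and 2723 unadjusted. The libraries kept in that fit still differed in length slope by diet, as given above. Leaving out single libraries gave unadjusted counts from 143 (deficient-uninfected replicate 3) to 1157 (deficient-uninfected replicate 2), and without sufficient-uninfected replicate 2 Gm8399 alone was called (log2 change -2.39, adjusted p = 2.02e-05). The smallest p on the higher side belonged to Gm11407 (0.95, SE 0.24), Gm10676 (1.39, SE 0.35), the adhesion receptor gene Adgrg5 (1.1, SE 0.28), the melanocortin receptor gene Mc5r (0.81, SE 0.21) and 9130213A22Rik (1.08, SE 0.29). On the lower side were Gm8399 (-2.2, SE 0.44), Rps2-ps10 (-5.01, SE 1.21), Ngp, the orphan receptor gene Gpr62 (-0.64, SE 0.17) and the detoxifying enzyme gene Glo1 (-0.72, SE 0.18). Glo1 stood at 186 ± 22.7, 110 ± 29, 106 ± 43.8 and 70.7 ± 4.4 CPM in sufficient-uninfected, sufficient-infected, deficient-uninfected and deficient-infected brains (SD, n = 4 each).

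The other 30 lists were not called for diet, with means from -0.35 (pituitary) to 0.22 (insulin and IGF axis) and adjusted p from 0.0587 to 0.995. Nearest were the insulin and IGF axis (0.22, adjusted p = 0.0587), with Irs1 (0.73, SE 0.34) and Igf1r (0.91, SE 0.57), and the amino acid response and ATF4 targets (0.13, adjusted p = 0.0704), with Chac1 (0.78, SE 0.27) and Aldh1l2 (0.29, SE 0.14). Mean and median differed in sign for pituitary (median 0.07) and eye (mean -0.06, median 0.08), and the test pointed down for endothelium and pericytes with a mean of 0.11. For diet 11 lists were called without the 4 libraries, 5 of them among the 8, and with the offset 7, all among the 8. The amino acid list without the 4 libraries was at 0.26 (adjusted p = 1.25e-08, 0.63 with an estimated correlation and 0.0345 with fry), and 18 members passed over the list alone, all higher, against 0 over all genes. Deficient-uninfected replicates 3 and 4 stood at 0.22 and 0.6, but the deficient-infected libraries at -0.14 to 0.09. The libraries of the sufficient diet kept in that fit stood at -0.17 to 0.02. Imprinted growth genes, at 0.2 in all 16 libraries (adjusted p = 0.131), were at 0.22 without the 4 (adjusted p = 0.0069, 0.415 estimated and 0.0345 with fry). With the length and GC offset on all 16 libraries they were at 0.05 (camera adjusted p = 0.186). Zim1 (0.42, SE 0.23) and Usp29 (0.45, SE 0.25) led that list in all 16 libraries. Also called without the 4 libraries were GABAergic neurons (-0.26, adjusted p = 0.00136), erythroid cells (-0.67, 0.00522), the insulin and IGF axis (0.17, 0.018) and monoaminergic neurons and receptors (0.24, 0.0396), each at 0.662 with an estimated correlation.

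The third question is whether the effect of infection differed between the diets. For interferon-stimulated genes it did by camera: infected minus uninfected, the list mean was 0.31 on the sufficient diet and -0.29 on the deficient diet, neither tested alone, a difference of -0.6 with 18 of 20 members lower (camera adjusted p = 9.58e-09, and 0.204 with an estimated correlation). Ifi44 (-1.71, SE 0.67), Rtp4 (-0.9, SE 0.42), Isg15 (-1.38, SE 0.66) and Ifit3 (-1.86, SE 0.98) led the list at low levels. Isg15, a ubiquitin-like antiviral protein, stood at 1.25 ± 0.786, 1.33 ± 0.507, 1.33 ± 0.6 and 0.542 ± 0.229 CPM in the sufficient-uninfected, sufficient-infected, deficient-uninfected and deficient-infected groups (SD, n = 4 each). This list kept its call without the 4 libraries (-0.57, adjusted p = 8.46e-07, and 0.208 estimated) and without any single library (-0.7 to -0.45), but 0 members passed over the list alone or over all genes.

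Likewise untested within a diet, mitochondrially encoded genes were at 0.55 and -0.24 on the sufficient and deficient diets, a difference of -0.79 in which all 13 members were lower (adjusted p = 1.28e-08, and 0.353 estimated; without the 4 libraries -0.41, adjusted p = 0.0841; over single libraries left out -1.05 to -0.6). mt-Atp8 (-1.54, SE 0.52), mt-Atp6 (-1.53, SE 0.56), mt-Co2 (-1.56, SE 0.57) and mt-Co3 (-1.62, SE 0.69) led it. Over the libraries these had 1.05 to 5.8, 3.84 to 25.1, 4.92 to 34 and 8.45 to 91.1 CPM, against 319 to 1220 CPM for mt-Nd5. Whether reads shared with other loci lowered or shifted their counts was not tested. Erythroid genes were at -0.37 and 0.47, a difference of 0.84 with all 10 members higher (adjusted p = 5.33e-05, and 0.353 estimated). It ran from 0.5 to 1.26 over single libraries left out and was 1.65 without the 4 libraries (adjusted p = 1.28e-09, and 0.298 estimated). The list was highest in sufficient-uninfected replicates 2 (1.24) and 4 (0.92) and deficient-infected replicate 1 (1.12), and at most at 0.43 in the other 13, with the other deficient-infected libraries at 0.2, -0.59 and -0.35. Slc4a1 (2.22, SE 1.12), Klf1 (1.08, SE 0.61) and Hemgn (2.1, SE 1.25), which serve red blood cells, were among its leading members. Meninges, bone and cartilage genes were at 0.42 and -0.23, a difference of -0.65 (adjusted p = 0.000478, and 0.563 estimated), led by the collagens Col1a2 (-1.27, SE 0.82) and Col3a1 (-1.09, SE 0.73) with Ogn (-0.81, SE 0.56) and Sp7 (-1.1, SE 0.82). Over single libraries left out it ran from -0.92 to -0.32, and without deficient-infected replicate 1 the call was lost (-0.32, adjusted p = 0.0864).

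The other 7 called lists each depended on several single libraries. Leaving out each of the 16 in turn, the cerebellum and hindbrain list kept its call 11 times (-0.06 to 1.34), oxidative phosphorylation 10 times (-0.13 to 0.42), the unfolded protein response 10 times (0.00 to 0.12), the cell cycle 9 times (0.02 to 0.21), endothelium and pericytes 8 times (-0.18 to 0.37), cholesterol synthesis 7 times (0.05 to 0.17) and the p53 targets 5 times (0.02 to 0.17). Fetal sex as a covariate ended the calls of cholesterol synthesis (adjusted p = 0.109), endothelium and pericytes (0.0622) and the unfolded protein response (0.0517). The length and GC offset ended those of the cell cycle (0.0522), cholesterol synthesis (0.0573) and the p53 targets (0.077). No call was left without the 4 libraries for the cell cycle (0.00, adjusted p = 0.808), endothelium and pericytes (0.01, 0.672), the p53 targets (0.09, 0.126) and the unfolded protein response (0.06, 0.163). Cerebellum and hindbrain was at 0.8 (adjusted p = 0.0153, and 0.835 estimated), at -0.06 without deficient-uninfected replicate 1 (adjusted p = 0.919). Without the 4 libraries it was called in the opposite direction, at -0.65 (adjusted p = 0.00499, and 0.732 estimated). Its members with the smallest p were Egr2 (-0.61, SE 0.33), Cbln1 (0.39, SE 0.3; -0.06 without the 4 libraries), Atoh1 (-1.62, SE 1.28) and Barhl1 (-0.6, SE 0.85; 0.13 without deficient-uninfected replicate 3). Oxidative phosphorylation was at 0.13 (adjusted p = 0.0291, and 0.957 estimated) and turned to -0.11 without sufficient-uninfected replicate 1 and -0.13 without deficient-uninfected replicate 3. It was led by Atp5a1 (0.35, SE 0.26), Ndufv1 (0.44, SE 0.34), Ndufa13 (0.38, SE 0.34) and Atp5b (0.33, SE 0.34; -0.01 without the 4 libraries). Endothelium and pericytes were at 0.19 (adjusted p = 0.0291, and 0.788 estimated; -0.18 without deficient-uninfected replicate 2), led by Cldn5 (0.39, SE 0.27), Kcnj8 (0.51, SE 0.4), Rgs5 (0.31, SE 0.27; -0.02 with voom weights) and Ramp2 (0.33, SE 0.28).

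Of the 4 remaining, the unfolded protein response was at 0.09 (adjusted p = 0.0319, and 0.353 estimated), led by Dnajb11 (0.35, SE 0.18), Derl3 (-0.93, SE 0.58), Pdia6 (0.33, SE 0.23) and Ssr1 (0.25, SE 0.2). Cholesterol synthesis was at 0.11 (adjusted p = 0.0326, and 0.695 estimated), led by Hmgcs1 (0.55, SE 0.27), Cyp51 (0.29, SE 0.23), Nsdhl (0.32, SE 0.29) and Mvk (0.32, SE 0.29). The cell cycle was at 0.12 (adjusted p = 0.0326, and 0.788 estimated), led by Mcm5 (0.47, SE 0.3), Cdc20 (0.38, SE 0.27), Mcm7 (0.43, SE 0.37) and Mcm3 (0.34, SE 0.31). The p53 targets were at 0.1 (adjusted p = 0.0427, and 0.353 estimated), led by Pmaip1 (0.55, SE 0.29), Phlda3 (0.36, SE 0.22; -0.06 without the 4 libraries and with the offset), Aen (0.25, SE 0.18) and Bax (0.28, SE 0.36). The 27 lists not called for the interaction had means from -0.38 to 0.39 and adjusted p from 0.123 to 0.978. Among them mean and median differed in sign for choroid plexus and ependyma (-0.02 and 0.05), neural progenitors and radial glia (-0.01 and 0.01) and skin and oral or nasal epithelium (-0.02 and 0.07). The test pointed up, against the mean, for hypothalamic neurons (-0.07), one-carbon metabolism and DNA methylation (-0.04), the progenitors and the epithelium. With fry 0 of the 38 lists passed (smallest adjusted p = 0.92). Of lists not called with all 16, leaving out the 4 libraries brought calls for GABAergic neurons (0.44, adjusted p = 4.37e-07), glutamatergic neurons (0.41, 2.33e-05), microglia and macrophages (-0.44, 3.39e-05), ribosomal proteins (0.12, 0.00954), hypoxia and glycolysis (0.13, 0.0156) and the amino acid list, all at 0.208 to 0.84 with an estimated correlation. The offset brought 1, microglia and macrophages (-0.23, adjusted p = 0.031).

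For the interaction edgeR called 0 genes (smallest adjusted p = 1), with 172 at an unadjusted p under 0.05 against 884 expected by chance. DESeq2 called 3, Gm6166, Dynlt1a and Gm8399, and voom with weights called 0. Unadjusted, there were 1170 genes with voom weights, 1010 with svaseq and 158 with fetal sex as a covariate. The edgeR counts without the 4 libraries were 0 adjusted and 491 unadjusted. The unadjusted count was 309, 282 and 304 without sufficient-uninfected replicates 1, 2 and 4. Without its replicate 2, Gm8399 alone was called (log2 difference 4.31, adjusted p = 7.25e-05). The 10 genes with the smallest p were mostly pseudogenes and unnamed loci. Higher were Gm8399 (3.92, SE 0.87), A830052D11Rik (1.96, SE 0.48), Gm44214 (2.18, SE 0.56), Tma16 (1.13, SE 0.3) and Cage1 (0.99, SE 0.3). Lower were Gm6166 (-6.98, SE 1.53), Dynlt1a (-9.62, SE 2.13), Anp32-ps (-2.92, SE 0.72), Gm10925 (-2.82, SE 0.71) and Gm4895 (-2.16, SE 0.56). Dynlt1a, a dynein light chain gene with near-identical copies, had 8.5 to 23.3 CPM in 4 libraries of 2 groups and at most 1.2 CPM in the others.

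Within single levels, edgeR again called 0 genes in each of the 4 comparisons. By infection on the sufficient diet, 2600 genes had an unadjusted p under 0.05 (smallest adjusted p = 0.336), DESeq2 called 2 (Gm8399 and Glns-ps1) and voom 0. With fetal sex as a covariate, svaseq and voom weights the unadjusted count was 1184, 797 and 522. The unadjusted count was 447 without sufficient-uninfected replicate 1 and 460 without its replicate 3. It was 5859 without its replicate 2, where Gm8399 was called (adjusted p = 2.38e-06), and 4742 without its replicate 4. Without sufficient-infected replicates 1 to 4 in turn it was 1398, 1335, 750 and 1494. On the deficient diet it was 1194 (smallest adjusted p = 0.541), DESeq2 called 3 (Gm12586, Prss56 and Tnnt1) and voom 754. The same 3 settings gave 446, 432 and 5543. The edgeR unadjusted count was 290 without deficient-uninfected replicate 2, 505 without its replicate 1, 3697 without its replicate 3 and 2229 without its replicate 4. Without deficient-infected replicates 1 to 4 in turn it was 409, 2061, 473 and 571. Without the 4 libraries and with the offset, edgeR called Chac1 (log2 change -1.68, adjusted p = 0.0253). With all 16 libraries Chac1 was at -1.03 (SE 0.39, adjusted p = 0.541), and without the 4 libraries but with no offset the smallest adjusted p of any gene was 0.0681.

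By diet in uninfected dams, 427 genes had an unadjusted p under 0.05 (smallest adjusted p = 0.303), DESeq2 called 3 (Gm8399, Gm6166 and Gm6505) and voom 0. Unadjusted, fetal sex as a covariate, svaseq and voom weights gave 350, 1618 and 2060. The unadjusted count was 1414 without sufficient-uninfected replicate 2, where edgeR called Gm8399 (adjusted p = 1.27e-06), 240 and 1168 without its replicates 3 and 4, and 1002, 1225 and 220 without deficient-uninfected replicates 1, 2 and 3. By diet in infected dams, 136 genes had an unadjusted p under 0.05 (smallest adjusted p = 0.99), DESeq2 called 1 (Gm12586) and voom 6491. Fetal sex as a covariate, svaseq and voom weights gave 127, 302 and 8849 unadjusted. No library there had a slope under -0.2, but the length slopes still differed by diet. They were 0.03 to 0.18 on the sufficient diet and 0.25 to 0.3 on the deficient diet, apart from deficient-infected replicate 2 at -0.02. In the voom fit that library had a weight of 0.406, the lowest of the infected-dam libraries. The voom calls therefore do not separate diet from length. Without deficient-infected replicates 1 and 2 the unadjusted count was 74 and 229. Gm12586, a gene near the detection limit, had 0.482 to 2.78 CPM in 5 libraries and no count in the other 11, which allows up to 0.145 CPM. These genes of the other tools were named after their values were seen.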

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

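The tests of transcript length and GC content, of length classes and of infection for the 4 libraries' distance, those of each library alone, of fetal sex and of diet for the amino acid list, and those of inherited variants and of diet or infection for the on-and-off genes were chosen only after the results were seen.

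The distance of 4 uninfected-dam libraries on the first principal component followed transcript length. The fitted trend with annotated length and GC content was not its whole cause. With that trend removed, the component still held 52.8% of the variance, against 68.6% before, and the 4 libraries still scored lowest. Lengths were those of annotated transcripts, which may not be the ones expressed here. A length effect that the fitted trend misses therefore stays open. An excess of a few abundant transcripts would shift all other genes alike, short and long. Without the 50 most abundant genes the component held 68.5% of the variance, a share so few genes can hardly move. Median log2 values of genes up to 1000 and over 8000 bases then differed by 1.32 to 2.66 in the 4 libraries and by -1.36 to 0.18 in the other 12. The 4 were set apart by their length slope, so their contrast with the 12 only restates that choice. The gap between short and long genes is not a like shift, and to that extent it argues against such an excess as the whole cause. Maternal infection stays open too, since 4 of the 8 uninfected-dam libraries inside the range of the infected-dam ones only restates that the other 4 stood apart. A difference in RNA state or library batch that the labels do not record may also underlie it, and these cannot be told apart with all 4 libraries at 1 infection level.

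The amino acid response and ATF4 targets were high in deficient-uninfected replicates 3 and 4 (0.22 and 0.6 on the log2 scale), both male and without a steep length slope. Removing the length and GC trend left replicate 4 at 0.55, above all others, which argues against that trend for it, and put replicate 3 at 0.15, under sufficient-uninfected replicate 1 at 0.19, so for replicate 3 it stays open; their mean of 0.35, from 0.41, is carried by replicate 4. Fetal sex as the whole cause of the pattern is argued against by replicate 4: the other 7 males reached 0.02 without the offset and 0.19 with it. They averaged 0.01 (SE 0.04) and 0.1 (SE 0.06) above the 7 females, where replicate 3 lay 0.29 and 0.25 above the females. These SE are of means and not of single males. With the offset replicate 3 (0.15) lay under the highest of the other males, so for replicate 3 sex stays open. Diet stays open: 2 deficient-uninfected libraries lay above the highest sufficient-uninfected one (0.02) without the offset and 1 with it, which only restates the pattern. A response to protein shortage that varied between litters, or a difference in handling, could also be behind it, and neither was tested.

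In 42 of 14944 genes with a mean of at least 1 CPM, at least 3 libraries lay above and at least 3 below a gap of 2 or more on the log2 scale. Pseudogenes made up 40.5% of them and 3.22% of the genes tested, a ratio of 12.6 (Fisher's exact p = 3.92e-15), which is consistent with reads shared between near-identical copies. Of the 42 genes, 0 divided the libraries exactly by diet or infection. Inherited variants of an outbred stock could also give such patterns, and 8 pairs of the genes were neighbours within 10 genes, where 95% of 1000 random sets had at most 2 and the highest 4, but neighbouring copies that share reads would do the same and this cannot be told apart here. That count leaves out 5 sex-linked and 7 liver genes. With them it was 23 pairs, and they were left out after the 23 had been seen.

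Of 184 groups of 4 values, 16 held a library beyond the limit of Dixon's ratio for 4 values, which chance passes in 5% of groups. Glns-ps1 stood at -1.12 (log2 CPM) in sufficient-uninfected replicate 3 against -1.88 to -1.82, and at -1.14 in deficient-infected replicate 4 against 1.46 to 1.84. Dmc1 stood at -1.32 in sufficient-infected replicate 3 against -1.25 to -1.24. Gm8399 stood at 1.68 in sufficient-uninfected replicate 2 against 5.97 to 6.43, and Rps2-ps10 at 5.23 in that group's replicate 4 against -1.09 to -0.69. Cage1 stood at 1.2 in deficient-uninfected replicate 4 against 1.88 to 1.95. Gm6166 stood at 1.82 in sufficient-infected replicate 3 against 5.75 to 5.89, and at 5.26 in deficient-infected replicate 4 against 0.84 to 1.42.

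Among list means, sufficient-infected replicate 3 stood at -1.78 for cerebellum and hindbrain against 0.3 to 0.64, at -0.49 for oxidative phosphorylation against -0.16 to -0.1, and at 0.4 for endothelium and pericytes against -0.05 to 0.01. Deficient-infected replicate 2 stood at 0.16 for cerebellum and hindbrain against 1 to 1.16, at -0.18 for synapse genes against 0.43 to 0.53, and at 0.11 for the unfolded protein response against -0.12 to -0.09. Its length slope was -0.02 against 0.25 to 0.3. Interferon-stimulated genes stood at -0.46 in deficient-infected replicate 3 against -0.21 to -0.17.

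The change by infection differed between the diets for 11 lists by camera's interaction test, and for 0 of them with an estimated correlation or fry. The differences (deficient minus sufficient) were -0.79 for mitochondrially encoded genes, -0.65 for meninges, bone and cartilage, -0.6 for interferon-stimulated genes, 0.84 for erythroid cells, 0.8 for cerebellum and hindbrain and 0.19 for endothelium and pericytes. They were 0.13 for oxidative phosphorylation, 0.12 for the cell cycle, 0.11 for cholesterol synthesis, 0.1 for p53 targets and 0.09 for the unfolded protein response.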

How the results depend on the processing

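The fits with a length and GC offset, those without the 4 libraries of steep length slope, and DESeq2 with independent filtering were chosen only after the results were seen. The count of 0 called genes in each of the 7 comparisons held under relative log expression scaling, no filter, the mean CPM filter, non-robust dispersion, the sex covariate, svaseq with 1 surrogate variable, either offset, the fit without the 4 libraries, and, for the 4 simple effects, the fit of the groups compared alone. With the replicate number as a block, the count was also 0 in all 7 comparisons and the lists called were 5, 9 and 10, with the p53 targets lost for the interaction (adjusted p = 0.0509). Whether the shared numbers pair the samples stays open. Of 24 correlations between same-numbered samples 11 exceeded 0.1 (-0.7 to 0.68), and 6 of 16 samples correlated best with their own number. The correlations were taken without the offset and so carry the length trend. They can therefore neither show nor exclude a litter or batch shared by same-numbered samples. Leaving out 1 library gave 0 to 1 called genes. The 1 was Gm8399 without sufficient-uninfected replicate 2, in the 3 factorial comparisons, infection on the sufficient diet and diet in uninfected dams.

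DESeq2 called 7, 2, 3, 2, 3, 3 and 1 genes for infection, diet, interaction, infection on the sufficient diet, infection on the deficient diet, diet in uninfected dams and diet in infected dams. With independent filtering the infection count was 736, and the others were again 2, 3, 2, 3, 3 and 1. Of the 736, adjusted p lay between 0.0478 and 0.05, 12 genes were higher and 724 lower, and 76.5% had transcripts under 2000 bases, against 22.8% of genes tested. That filter left 11318 genes without an adjusted p, so fewer genes were tested. Voom with sample quality weights called 2563 genes for diet, 754 for infection on the deficient diet (324 higher, 430 lower) and 6491 for diet in infected dams (3656 higher, 2835 lower), with weights from 0.0895 to 10.8. Without the 4 libraries and with the offset, 1 gene was called for infection on the deficient diet. For the DESeq2, voom and offset counts the cause was not tested.

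The 24 list calls became 0 with an estimated correlation and 0 with fry, 37 without the 4 libraries and with the offset, 1 without them with an estimated correlation and 2 without them with fry. Camera on ranks ended 1 call, cerebellum and hindbrain for infection (adjusted p = 0.0824). The unadjusted infection count was 4324 with the offset and 4417 with its longest-transcript version. Some lists turned direction, and the cause was not tested. Without the 4 libraries the synapse list was at -0.02 for infection with or without the offset, with an estimated correlation and with fry, and at 0.00 for diet with the offset. Cerebellum and hindbrain was at -0.65 for the interaction without them, with an estimated correlation and with fry, at -0.68 with the offset, and from -0.06 to 1.34 over single libraries left out, lowest without deficient-uninfected replicate 1. Endothelium and pericytes ranged likewise from -0.18, without deficient-uninfected replicate 2, to 0.37. Oxidative phosphorylation ranged from -0.13 to 0.42, and was at -0.11 and -0.06 without sufficient-uninfected replicates 1 and 3, and -0.13 without deficient-uninfected replicate 3. Direction of a list is that of the test, so means of -0.03 and -0.05 for oxidative phosphorylation (without deficient-uninfected replicate 4 or deficient-infected replicate 2) and -0.01 for endothelium and pericytes (without the 4 and with the offset) count as lost calls, since the test still pointed up.

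Single genes also turned. For infection, Reln was at -0.11 with svaseq, 0.00 without the 4 libraries, -0.03 with the offset, -0.02 with its longest-transcript version and -0.06 without the 4 and with the offset. Lhx5 was at -0.04 with svaseq, -0.03 without the 4 and -0.01 with the offset too, and En1 at -0.02, -0.07 and -0.05 in the same fits. Calm2 was at 0.02 with the offset and 0.01 with the longest-transcript version, where Rap1a was at 0.02. For diet, Syp was at 0.00 with voom weights. For the interaction with voom weights, Cbln1 was at -0.22, Rgs5 at -0.02 and Atp5b at -0.07. Without the 4, Cbln1 was at -0.06 and Atp5b at -0.01, and with the offset too they were at -0.11 and -0.04 and Phlda3 at -0.06. Barhl1 was at 0.01 with svaseq and ranged from -0.93 to 0.13 over single libraries left out, highest without deficient-uninfected replicate 3. In all, 25 values of single genes and 14 of lists turned direction, and 197 of lists lost their call, while 47 values of single genes gained one, and 3588 of genes and 483 of lists kept direction and side of the threshold. Groups of 4 libraries, and transcript lengths from a later annotation, limit all of these comparisons.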

Other observations

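Of the tests below, the liver genes, growth hormone and Slc7a11 were chosen only after the results were seen, and the counts of splits were planned.

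Genes that the fetal liver secretes varied together between libraries. Albumin (Alb) had 39 to 166 CPM in 6 libraries: sufficient-uninfected replicates 3 and 4, sufficient-infected replicate 2, deficient-uninfected replicate 2 and deficient-infected replicates 1 and 2. It had 0.0742 to 8.24 CPM in the other 10. In 4 of the 6, all but the deficient-infected ones, the neutrophil granule and alarmin list was also high, at 0.74 to 1.31 against at most 0.19 elsewhere. Alpha-fetoprotein (Afp) had 12.3 to 49.3 CPM in the 6 and 0.26 to 2.57 CPM elsewhere, and Ahsg 10.4 to 50.1 against 0.0371 to 2.5 CPM. The fibrinogen genes Fga and Fgb had 5.81 to 22.1 and 4.66 to 21 CPM in the 6, and at most 1.17 and 0.903 CPM elsewhere. Growth hormone (Gh), a pituitary product, had 416 CPM in sufficient-uninfected replicate 1, 330 in deficient-uninfected replicate 4 and 67.4 in sufficient-infected replicate 4, against at most 7.01 CPM in the others. The cystine transporter gene Slc7a11, a target of ATF4, had 8.81 to 24.9 CPM in 7 libraries and 172 to 649 CPM in 9, with both levels present in each group.

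Other divisions of the samples gave results as large as the real one in each comparison, so chance is not excluded for any of them. For infection, 5 of 100 permuted labellings, the real one included, had at least as many genes at an unadjusted p under 0.05 (4891, highest other 9784). For diet 45 did (324, highest other 9305) and for the interaction 66 (172, highest other 11596). As many gene lists were called in 96 labellings for infection (5, highest other 18), 78 for diet (8, highest other 19) and 36 for the interaction (11, highest other 19). At an adjusted p the real counts were 0, which all 100 labellings reached, and the highest others were 3578, 2292 and 10659.

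Within a level, the 35 ways to divide 8 libraries gave at least as many genes at an unadjusted p in 5 for infection on the sufficient diet (2600, highest other 2914), 6 for infection on the deficient diet (1194, highest other 5778), 18 for diet in uninfected dams (427, highest other 12671) and 6 for diet in infected dams (136, highest other 400). Each division was applied to the 8 libraries of the other level at the same time, in a joint fit with a shared spread. The counts for a level therefore also depend on how the other level was divided. At an adjusted p all 35 reached the real count of 0, with highest others of 0, 0, 12189 and 0. Labellings that call as many as 10659 or 12189 genes where the real one calls 0 point to a structure of the samples that the division by diet and infection does not follow. All 4 libraries of steep length slope come from uninfected dams, so these counts are no evidence against a part played by infection.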
